A study of Mus musculus with 2 samples.

How the data were processed

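The data are long-read RNA-seq of total RNA from the adrenal gland of C57BL/6J mice, with 2 biological replicates in 1 group. In long-read RNA-seq a cDNA molecule is read from end to end, so that 1 read can show which exons of a gene were joined. Both replicates carry a description that names females, while their sex field reads not collected, and no age is given. The replicates come from different biosamples of the same strain. There is no second group, so no comparison between conditions was possible.

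Each library came with a table of transcript models and a matching model annotation. The deposited values are raw read counts per transcript model, per the file headers, and a model with no reads is not listed. The models were made with TALON for each library on its own, on mm10 with GENCODE M21, per the file headers and the accompanying sample notes. TALON is a program that assigns each read to an annotated transcript or to an unannotated model. The aligner, the read correction and the versions of the authors' tools are not given in the sources used here, nor are the sequencing platform and the cDNA preparation. The classes are those the tables give: annotated, incomplete match (the junctions of an annotated transcript in part), known splice sites in an unannotated combination, at least 1 unannotated splice site, antisense to a gene, intergenic, and genomic (mostly unspliced reads inside a gene). All 88152 models of replicate 1 and all 92074 models of replicate 2 had as many exons in the annotation as in the count table. Each of the 22139 annotated models counted was found in GENCODE M21 by its identifier. Gene bounds were taken from GENCODE M21, because 16214 of 55536 annotated genes had other bounds in the annotation of replicate 1. All coordinates are on mm10, counted from 1. The length of a model is that of the model as annotated, not of the reads.

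Counts of all models of a gene were summed. CPM, counts scaled to a common library total, were computed over all reads of a library, and values are given as the mean ± SD of 2 libraries. Replicate 1 held 810239 reads and replicate 2 held 587861, so that 3 reads, the most that a count of 0 allows, stood for 3.70 and 5.10 CPM. Shares in single libraries carry 95% Clopper-Pearson confidence intervals. Intervals and floors cover counting error only, since reads made by amplification are not independent molecules.

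Replicate 2 was compared with replicate 1 gene by gene for the 9809 genes with at least 10 reads over both. The test was the exact two-sided binomial test on the counts of a gene given their sum, with the share set by TMM-scaled library sizes (edgeR 4.0.16) and Benjamini-Hochberg adjustment at 0.05. Such a test compares these libraries and their reads. It says nothing about conditions, and without replicates within each library it has no replicate check. Log2 ratios used a pseudocount of 0.5 reads. Folds with intervals are ratios of TMM-scaled counts with the interval of that binomial share. A fold against 0 reads is a lower bound, computed with 3 reads per library in place of 0. It takes the other count as exact, so the binomial interval can allow a smaller fold. Because TMM and CPM scale differently, the ratio of 2 CPM values differs from the fold of the test by a constant factor for all genes. The spread between the libraries was also estimated as a common dispersion by edgeR under an intercept-only design, on the genes kept by filterByExpr, and given as a biological coefficient of variation.

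A lowess curve with a span of 0.3 described the log2 ratio by the length of the most used annotated model, over genes with at least 20 reads. For the length-adjusted test the share of each gene was set from that curve. Of the 9809 genes, 9173 had such a length. In a few genes the annotated model is far shorter than the gene, and their adjusted values are then not meaningful.

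Isoform use was compared over genes with at least 10 reads in each library. Unannotated models have identifiers of their own in each library, so spliced models were matched by their chain of junctions, annotated models by identifier, and all unspliced unannotated models of a gene were pooled. Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment at 0.05, compared the reads of the most used model with those of all other models of the gene, for genes with at least 2 models.

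The 22 gene lists were fixed before the data were examined, as were the tests, the thresholds, the rule for named genes and most alternatives. The lists were steroid synthesis, steroid cell regulators, cholesterol supply, zona glomerulosa, zona fasciculata, X-zone, chromaffin, sympathetic neuron, Schwann, capsule and fibroblast, endothelial, macrophage, lymphocyte, erythroid, adipocyte, kidney, liver, muscle, immediate early and stress, mitochondrial genome, sex-linked, and splicing factor and RNA-binding. For a list with at least 3 tested members, the median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins (seed 1), as a description of these libraries.

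The text names genes by this rule. It takes the 15 genes with the highest mean CPM, members of the lists with 2 to 4 examples each, and the 8 largest folds in each direction among called genes with at least 50 reads over both. It also takes list members with at least 10 reads in each library for their most used model, genes among the 10 of highest mean CPM whose most used model is unannotated, the 8 largest differences in isoform use, and the 5 intergenic and 5 antisense spliced loci of highest mean CPM seen in both libraries. Some genes that overlap a named gene, or whose sequence is close to it, are given beside it, and Dbh, Npy and Pnmt, chosen after their values were seen, are marked as such.

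The steps were tested on simulated data. Those of the gene test, the isoform test and the length trend were drawn from the real means and library sizes. The list check used normally distributed log2 ratios, and the dispersion check drew both libraries from the same real means. The simulations of the gene test, the isoform test and the length trend held counting error only, with no spread between libraries. The simulated trend was a straight line in log2 length. Their false calls therefore need not hold for the real libraries. The gene test recovered 27.3% of genes changed 2-fold among 9476 genes, with 4 false calls. In further simulations it recovered 64.9% at 4-fold, with 5 false calls, and 84.7% at 8-fold, with 3. The isoform test recovered 52.5% of 200 genes shifted by 40 percentage points among 4733 genes, with 1 false call. A simulated length trend of slope 1.5 was fitted as 1.47, and its 4468 calls over 9173 genes became 0 after removal. Of 100 random lists without a shift, 5 fell outside the central 95%. A simulated coefficient of variation of 80% was estimated as 62.2%, and one of 20% as 19.3%, so large values were estimated too low in that setting. It held no length trend, so the same need not hold for the real libraries.

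Alternatives covered the scaling (DESeq2 1.42.0 size factors, total counts), the read minimum, the models counted, the total used for CPM, the thinning of the larger library, the matching of models and the leaving out of each library. The removal of the length trend, with either of 2 measures of length, and matching by junctions alone were chosen after seeing the data. The splice-site sequences of unannotated junctions were left out, since they need the genome sequence, which was not used here. Further tools were R 4.3.3, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.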

Results

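Transcript models of the mouse adrenal gland were counted in 2 long-read RNA-seq libraries, replicates 1 and 2 of a single group of C57BL/6J tissue. The adrenal gland holds a cortex, which makes steroid hormones, and a medulla, whose chromaffin cells make catecholamines. Replicate 1 held 810239 reads in 88152 models and 14982 annotated genes. Replicate 2 held 587861 reads in 92074 models and 13897 annotated genes. At least 10 reads fell on 7120 genes in replicate 1 and on 6590 in replicate 2. A single read made up 62.7% of the models in replicate 1 and 67.4% in replicate 2, which held 6.82% and 10.6% of the reads. Reads on annotated models had a median model length of 1648 nt in replicate 1 and 3052 nt in replicate 2.

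The libraries were first described as an inventory of adrenal transcripts. By mean level, genes of steroid synthesis took the highest ranks. Cyp21a1, the steroid 21-hydroxylase, came first with 27639 ± 5350 CPM (SD, n = 2), at rank 1 in replicate 1 and rank 2 in replicate 2, where Cyp11b1 was first. Cyp11b1, the 11-beta-hydroxylase of the glucocorticoid pathway, followed with 22490 ± 12120 CPM, and Star, which carries cholesterol into mitochondria, with 16511 ± 9728 CPM. Hsd3b1, the 3-beta-hydroxysteroid dehydrogenase, reached 9474 ± 6383 CPM, and Cyp11a1, the side-chain cleavage enzyme, 6929 ± 1600 CPM. The remaining genes among the 15 highest were Hspa8, Ftl1, Adh1, Fth1, Eef2, Scarb1, Fads2, Akr1b7, Chgb and Hsp90ab1. Their means ran from 9203 ± 5437 CPM for the chaperone Hspa8 down to 3375 ± 1304 CPM for the chaperone Hsp90ab1. Ranks differed widely for some of these: Ftl1 stood at rank 2 in replicate 1 and 185 in replicate 2, and Eef2 at 239 and 4. The 10 most abundant genes of each library took 13.0% of reads in replicate 1 and 12.5% in replicate 2.

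On mm10, Cyp21a1 (ENSMUSG00000024365.9) lies on chromosome 17 from 34801348 to 34804561. Cyp11b1 (ENSMUSG00000075604.5) lies on chromosome 15 from 74834125 to 74841643, and Cyp11b2 (ENSMUSG00000022589.7) beside it from 74851010 to 74856318. Star (ENSMUSG00000031574.8) lies on chromosome 8 from 25806555 to 25815982, Hsd3b1 (ENSMUSG00000027871.16) on chromosome 3 from 98852194 to 98859794, and Cyp11a1 (ENSMUSG00000032323.13) on chromosome 9 from 58006411 to 58027023. Cyp11b1 and Cyp11b2 are close paralogs, and Cyp21a1 has a pseudogene copy, so their split of reads is uncertain.

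The steroid synthesis list, with 14 of 15 genes detected, held 8.61 ± 0.868% of all reads (n = 2). The chromaffin list, with 18 of 18 genes detected, held 1.07 ± 0.0991%. The reads of the former stood to those of the latter as 8.01 (95% interval 7.82 to 8.19) in replicate 1 and 8.10 (7.90 to 8.31) in replicate 2, a difference within counting error. Both totals join genes of unequal model length that moved in opposite directions. Log2 ratios of replicate 2 over replicate 1 were 0.81 for Star and -1.97 for Hsd3b1, and 0.87 for Chgb and -1.67 for Th. The equal totals therefore do not show that cortex and medulla were in the same balance. Among chromaffin genes, the granins Chgb and Chga and the related Scg2 led with 3538 ± 2175, 2503 ± 56.9 and 1707 ± 439 CPM. Th, the rate-limiting enzyme of catecholamine synthesis, reached 868 ± 482 CPM. Cyp17a1, the 17-alpha-hydroxylase that the mouse adrenal lacks after fetal life, had 2 reads in replicate 1 and 0 in replicate 2, where 0 reads allow 5.10 CPM.

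**Figure D1:**
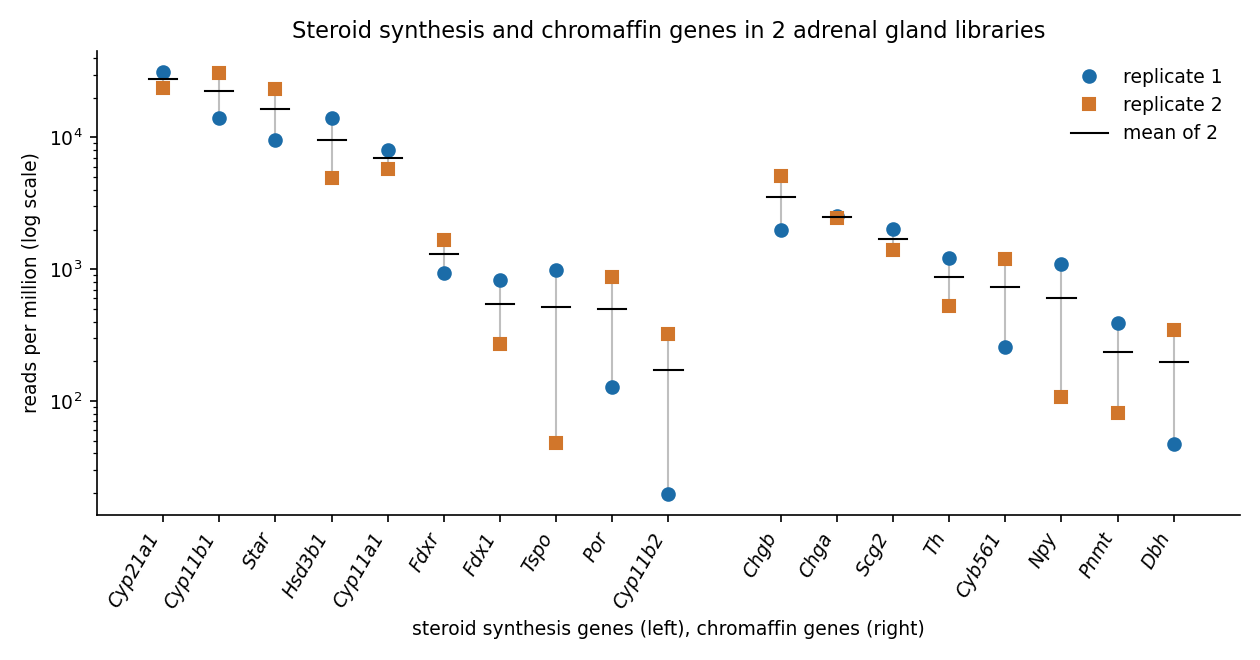
Reads in CPM (log scale) of the 10 steroid synthesis genes and the 8 chromaffin genes with the highest means in replicate 1 (circles) and replicate 2 (squares), with a bar at the mean of both. Cyp21a1 stands highest with a mean of 27639 CPM, and among the steroid synthesis genes shown Tspo and Cyp11b2 differ most between the libraries.

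Zone and cell type lists followed, with leading genes ranked by mean level, an order that need not hold in each library. The zona fasciculata list, genes of the glucocorticoid zone, held 2.75 ± 0.951% of reads, led by Cyp11b1 and by Akr1b7, an aldose reductase-like enzyme, at 3692 ± 2560 CPM. The zona glomerulosa list, genes of the aldosterone zone, held 0.124 ± 0.0535%, led by the potassium channel Kcnk3 at 456 ± 125 CPM and Dab2 at 277 ± 217 CPM. In replicate 2 Dab2 stood above Kcnk3, at 430 against 367 CPM. The X-zone list held 0.00680 ± 0.00120%, with Thrb at 56.4 ± 7.55 CPM and Akr1c18, a 20-alpha-hydroxysteroid dehydrogenase, at 9.96 ± 6.86 CPM. Of the Thrb reads, 45 of 50 in replicate 1 and 10 of 30 in replicate 2 were unspliced. The list of steroid cell regulators held 0.304 ± 0.200%, led by the kinase subunit Prkar1a at 1158 ± 758 CPM and the steroidogenic factor Nr5a1 at 1090 ± 1115 CPM. The cholesterol supply list held 0.933 ± 0.356%, led by the lipoprotein receptor Scarb1 at 4616 ± 3826 CPM and Apoe at 1834 ± 2312 CPM.

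Genes of other cell types were also detected. The erythroid list held 0.102 ± 0.113% of reads, with Hba-a1 at 366 ± 423 and Hbb-bs at 357 ± 391 CPM; Hba-a1 and Hba-a2 are near-identical copies, so their split is uncertain. The macrophage list held 0.0931 ± 0.0825%, with Lyz2 at 498 ± 563 CPM, and the endothelial list 0.0700 ± 0.0318%, with Eng at 148 ± 137 CPM and Plvap at 128 ± 42.0 CPM. The capsule and fibroblast list held 0.0372 ± 0.000429%, with Dcn at 124 ± 123 CPM, and the Schwann list 0.0256 ± 0.00487%, with Pmp22 at 128 ± 77.4 CPM. The adipocyte list held 0.0149 ± 0.0151%, with Plin1 at 52.6 ± 28.6 CPM, and the sympathetic neuron list 0.0106 ± 0.0110%, with Uchl1 at 47.2 ± 57.2 CPM. The lymphocyte list held 0.00715 ± 0.00699%, with Ighm at 62.0 ± 66.0 CPM. Of the kidney list only Cyp4b1 had reads, 33 in replicate 1 and 22 in replicate 2. The liver list had 3 reads and the muscle list 2 reads in replicate 1, and each had 0 in replicate 2.

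The mitochondrial genome list held 0.0632 ± 0.0812% of reads, led by mt-Co1 at 362 ± 473 CPM. The immediate early and stress list held 0.149 ± 0.103%, led on the mean by Jun, a transcription factor gene, at 333 ± 272 CPM. In replicate 1 Sgk1 had more reads than Jun (120 against 114), and in replicate 2 Hspa1a did (314 against 309). The splicing factor and RNA-binding list held 0.237 ± 0.100%, led by Srsf2 at 401 ± 360 CPM and Srsf5 at 362 ± 430 CPM. Of these, Srsf2 had more reads in replicate 1 (531 against 47) and Srsf5 in replicate 2 (392 against 86). Of the sex-linked list, the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in both libraries, and Xist had 154 reads in replicate 1 and 7 in replicate 2.

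The next question was how reads divided among structural classes. Annotated models took 73.4 ± 1.59% of reads (n = 2), and incomplete matches 10.3 ± 0.422%. Models with known splice sites in an unannotated combination held 4.73 ± 2.59% and models with an unannotated splice site 3.80 ± 1.88%. Genomic models held 4.04 ± 1.32%, antisense models 3.23 ± 1.81% and intergenic models 0.485 ± 0.183%. Models lacking the 5' end of the transcript (suffix matches) made up 54.3% of incomplete-match reads in replicate 1 and 56.6% in replicate 2.

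The libraries differed in these shares beyond counting error. Known sites in an unannotated combination held 2.90% of reads (95% Clopper-Pearson interval 2.86 to 2.93) in replicate 1 and 6.56% (6.50 to 6.62) in replicate 2. An unannotated splice site was present in models with 2.47% (2.44 to 2.505) and 5.14% (5.08 to 5.19) of reads. Antisense models held 4.51% (4.47 to 4.56) and 1.95% (1.92 to 1.99). Unspliced reads made up 14.4% of replicate 1 and 7.89% of replicate 2. With multi-exon models alone, the antisense mean was 0.117%, the intergenic 0.0304% and the genomic 0.0933%.

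**Figure D2:**
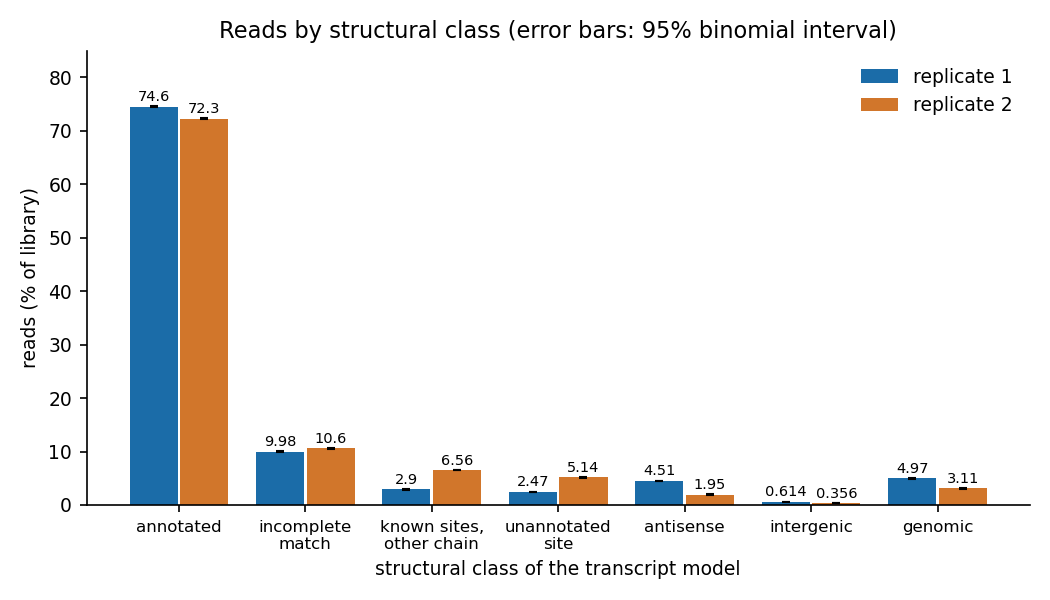
Share of reads (percent of the library) in each structural class of transcript model, for replicate 1 and replicate 2; error bars are 95% Clopper-Pearson intervals. Annotated models took 74.6% and 72.3%, and the shares of the unannotated splice combinations were larger in replicate 2.

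A further comparison set replicate 2 against replicate 1 gene by gene, which describes how far 2 libraries of the same tissue spread. Genes of short transcripts were higher in replicate 1 and genes of long transcripts higher in replicate 2. Ftl1, the ferritin light chain with a model of 968 nt, was 32.2-fold higher in replicate 1 (95% interval 29.0 to 35.8). Fth1, the ferritin heavy chain with a model of 929 nt, was 18.7-fold higher there (16.9 to 20.6). Eef2, the translation elongation factor with a model of 3089 nt, was 11.7-fold higher in replicate 2 (10.6 to 12.8), and Fads2, a fatty acid desaturase with a model of 3150 nt, 5.51-fold (5.11 to 5.95). Genes with models under 750 nt were higher in replicate 1 by a median of 18.2-fold (397 genes), and those from 3000 to 4000 nt higher in replicate 2 by a median of 2.98-fold (1480 genes).

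The exact binomial test with Benjamini-Hochberg adjustment called 6497 of 9809 genes (66.2%), of which 3004 were higher in replicate 2 and 3493 higher in replicate 1. At least 2-fold differences were found in 6042 of the called genes. The median model length was 3458 nt for genes higher in replicate 2 and 1536 nt for genes higher in replicate 1. Across 7416 genes, the log2 ratio and the length had a Spearman rho of 0.658, and the fitted trend took up 54.4% of the variance of the log2 ratio. Across genes, log2 CPM of the libraries had a Pearson r of 0.274 and a Spearman rho of 0.237; genes are not independent replicates. The common dispersion of edgeR corresponded to a biological coefficient of variation of 80.7% over the 4629 genes kept by the filter. Without the filter it was 94.3% (16674 genes), and with at least 50 reads over both it was 102.3% (4705 genes). The length trend was not removed for these values, so they do not measure biological spread alone. Scaled by total counts, the median log2 ratio of all genes was 0.42 in place of -0.01, and the share of called genes higher in replicate 2 was 55.9% in place of 46.2%; all folds here are relative to the TMM scale. With the length trend removed, 3890 of 9173 genes were called, 2646 of them in the same direction as before and 233 in the opposite direction.

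**Figure D3:**
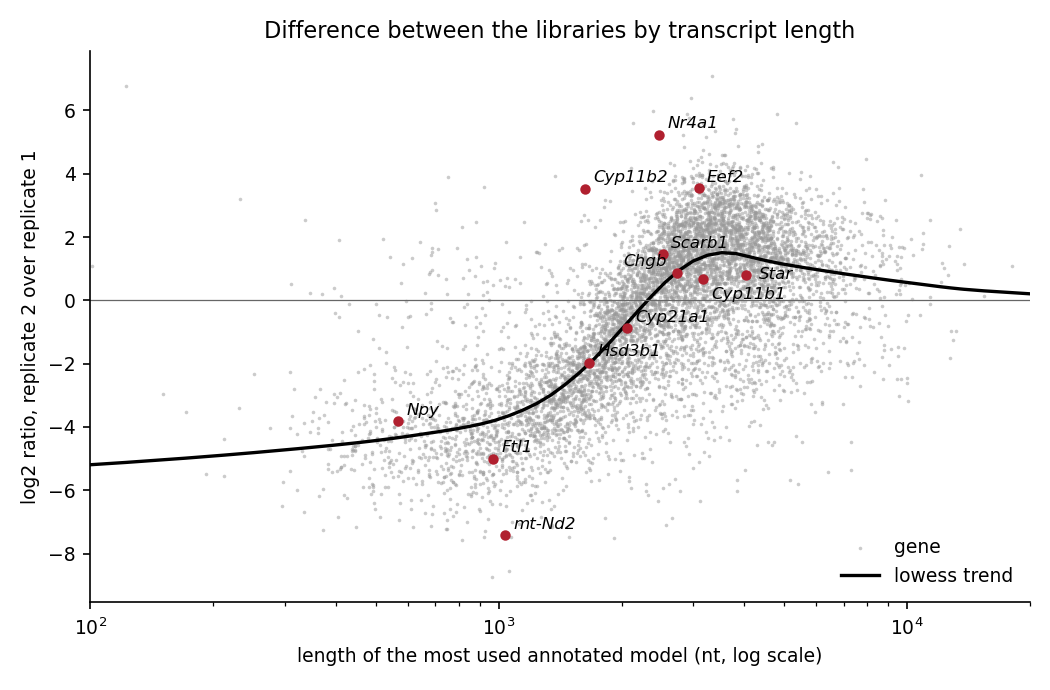
Log2 ratio of replicate 2 over replicate 1 against the length of the most used annotated model (nt, log scale) for genes with at least 20 reads, with the lowess trend as a line. Genes under 1000 nt lie mostly below 0 and genes from 3000 to 4000 nt mostly above, while Cyp11b2 and Nr4a1 lie far above the trend.

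Genes of the adrenal cortex went both ways. In the steroid synthesis list, 5 of 12 tested genes were higher in replicate 2 and 7 higher in replicate 1, and 12 were called when adjusted over the list alone. Cyp11b2, the aldosterone synthase, was 11.9-fold higher in replicate 2 (7.12 to 21.2; 16 and 191 reads; adjusted p 4.94e-38, exact binomial test with Benjamini-Hochberg adjustment), although its model is 1625 nt long. Cyp11b1 was 1.61-fold higher in replicate 2 (1.57 to 1.65), Star 1.75-fold (1.70 to 1.80), and Hsd3b1 was higher in replicate 1, with a log2 ratio of -1.97. Once the length trend was removed, Cyp11b1 and Star turned toward replicate 1, at -0.68 and -0.59, and Hsd3b1, at 0.05, was not called. The length used for Hsd3b1 was 1663 nt, but the last exon of its most read model in replicate 2 had 3312 nt. Its adjusted value is therefore uncertain. The reads of Cyp11b1 stood to those of Cyp11b2 as 705 to 1 in replicate 1 (434 to 1234) and as 95.6 to 1 in replicate 2 (82.9 to 111). In the zona glomerulosa list, 5 of 10 tested genes were higher in replicate 2, 3 in replicate 1 and 2 were not called, with 8 called when adjusted over the list alone. The angiotensin receptor Agtr1a had a log2 ratio of 1.40 and Dab2 one of 1.33, while Kcnk3 had -1.04. In the zona fasciculata list 3 of 8 were higher in replicate 2 and 5 in replicate 1, and in the X-zone list both tested genes were higher in replicate 1; 8 and 2 were called when adjusted over the list alone. After removal of the length trend, Akr1b7 of the zona fasciculata list turned toward replicate 2, at 1.13. Thrb of the X-zone list turned as well, at 0.97 for an annotated length of 1758 nt, which its unspliced reads need not have. Akr1c18, at 1.51, lost its call. Dab2 lost its call too, and Kcnk3 had -2.51 at an annotated length of 3811 nt, which its mostly unspliced reads need not have. Of the 8 glomerulosa calls 5 kept their direction and 3 were lost, and of the 8 fasciculata calls 1 kept it, 2 turned and 5 were lost. For steroid synthesis 7 of 12 calls kept their direction, 3 turned and 2 were lost.

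Nr4a1, a nuclear receptor induced by trophic hormones, was 39.6-fold higher in replicate 2 (21.3 to 83.2; 10 and 398 reads). Among steroid cell regulators, 3 of 9 were higher in replicate 2, 4 in replicate 1 and 2 were not called (7 called when adjusted over the list alone), with Nr5a1 at a log2 ratio of 2.17 and Mrap, the partner of the corticotropin receptor, at -3.67. After the length trend was removed, Nr5a1 had 0.98, Mrap was not called at 0.08, and Prkar1a turned toward replicate 1, at -0.49; 3 of the 7 calls kept their direction, 1 turned, 3 were lost and 1 was gained. In the cholesterol supply list 12 of 18 genes were higher in replicate 2 and 4 in replicate 1, with 2 not called and 16 called when adjusted over the list alone. Dhcr7, an enzyme of cholesterol synthesis, had a log2 ratio of 2.63, Scarb1 had 1.47, the cholesterol esterifying enzyme Soat1 had 0.79, and Apoe had -4.59. Length-adjusted, 11 of the 16 calls kept their direction, 5 were lost, Soat1 among them, and 1 was gained, which left 8 genes higher in replicate 2 and 4 in replicate 1, with Apoe at -1.79. In the immediate early and stress list, 5 of 10 were higher in replicate 2 and 1 in replicate 1, with 4 not called and 6 called when adjusted over the list alone. The heat shock gene Hspa1a was 15.6-fold higher in replicate 2 (9.94 to 25.9), or 6.60-fold with its length taken into account, and Jun and the kinase gene Sgk1 had log2 ratios of 1.43 and 1.17, of which Jun lost its call with the length trend removed and Sgk1 fell to 0.52. Of the 6 calls of this list 4 kept their direction, 2 were lost and 1 was gained. Hspa1a and its near-identical copy Hspa1b share sequence, so the split of their reads is uncertain.

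Genes of the medulla also went both ways. In the chromaffin list 4 of 17 were higher in replicate 2, 9 in replicate 1 and 4 were not called, with 14 called when adjusted over the list alone. Chgb had a log2 ratio of 0.87, Chga -0.52, Scg2 -1.001 and Th -1.67. As CPM, Chga was nearly equal, at 2544 and 2463. Chosen after their values were seen, Dbh, the dopamine beta-hydroxylase, had a log2 ratio of 2.40, the neuropeptide gene Npy -3.82, and Pnmt, which makes adrenaline, -2.72. Length-adjusted, Chga, Npy and Pnmt turned toward replicate 2, at 0.78, 0.52 and 0.73, and Chgb, at -0.03, and Th, at -0.20, were not called. Of the 13 chromaffin calls 5 kept their direction, 3 turned and 5 were lost, and with 1 gained, 5 genes were higher in replicate 2 and 4 in replicate 1. Pnmt reads stood to Th reads as 0.324 (0.285 to 0.369) in replicate 1 and 0.155 (0.112 to 0.210) in replicate 2. Chga reads stood to Chgb reads as 1.27 (1.19 to 1.36) and 0.485 (0.455 to 0.517). Both ratios join models of unequal length, and the length-adjusted values above go the other way. Sympathetic neuron genes were higher in replicate 1 in 4 of 4 tested, with Uchl1 at -4.00; 4 were called when adjusted over the list alone. Of the 4, 1 kept its call and direction with the length trend removed, 1 turned and 2, with Uchl1 at -0.21, lost their calls.

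Lists of other cell types also differed, and most of their calls did not outlast the removal of the length trend. In the macrophage list 2 of 9 were higher in replicate 2, 6 in replicate 1 and 1 was not called (8 called when adjusted over the list alone); lysozyme Lyz2 had a log2 ratio of -3.62 and the complement gene C1qa one of -4.16. Length-adjusted, Lyz2 had -0.55, C1qa, at -0.48, was not called, and 2 of the 8 calls kept their direction while 1 turned. In the erythroid list 4 of 5 were higher in replicate 1 (4 when adjusted over the list alone) and in the adipocyte list 5 of 6 (6 when adjusted over the list alone). With the length trend removed, no erythroid gene was called higher in replicate 1 and 3 were called higher in replicate 2, among them Hbb-bs at 0.82, and no adipocyte gene was called. In the endothelial list 4 of 8 were higher in replicate 2 and 2 in replicate 1 (6 when adjusted over the list alone), with Eng at 1.79 and Pecam1 at 2.16, while Plvap, at 0.21, was not called. With the length trend removed, 2 of the 6 calls kept their direction, Eng lost its call and Pecam1 had 0.72. Plvap, at 1.16, was the 1 call gained. In the capsule and fibroblast list 2 of 8 were higher in replicate 2 and 3 in replicate 1 (5 when adjusted over the list alone), with Col1a1 at 2.31 and Dcn at -2.94, and all 5 calls kept their direction with the length trend removed, at 1.33 and -1.24 for these genes. With 1 call gained, 3 genes were then higher in replicate 2 and 3 in replicate 1. Of the Schwann list 1 of 2 tested genes, Pmp22, was higher in replicate 1, and the lymphocyte list had Ighm alone, also higher there; each gave 1 call when adjusted over the list alone, and neither call held with the length trend removed. Cyp4b1, the tested gene of the kidney list, was not called in either adjustment, and no gene of the liver and muscle lists reached the minimum. The mitochondrial genes were higher in replicate 1 in 9 of 9 tested, all called when adjusted over the list alone, with mt-Co1 at -5.10. With the length trend removed, 3 of the 9 stayed called, with mt-Co1 at -2.72, and 3 that were not called turned positive. In the splicing factor list 6 of 14 were higher in replicate 2, 2 in replicate 1 and 6 were not called (8 when adjusted over the list alone), with Srsf5 at 3.04 and Srsf2 at -2.63; with the length trend removed 6 calls kept their direction, 2 turned and 5 were gained. The length-adjusted calls of this list were 7 toward replicate 2 and 6 toward replicate 1, with Srsf5 at 2.17 and Srsf2 at -1.39. Of the sex-linked list, Xist was higher in replicate 1 at -4.37 and Tsix was not called; 1 was called when adjusted over the list alone.

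Against 10000 random lists of matched expression, 5 lists had medians outside the central 95%. The cholesterol supply list had a median log2 ratio of 1.62 (percentile 99.2). The mitochondrial genome list had -4.87 (percentile 0.02), the adipocyte list -3.87 (0.05), the sympathetic neuron list -3.49 (0.99) and the macrophage list -3.04 (1.005). With the length trend removed, only the cholesterol supply list stayed outside, with 0.80 (percentile 97.7), and with the mean length of all models of a gene it too lay inside, with 0.60 (percentile 96.5). The remaining lists lay inside the central 95%, among them zona glomerulosa with 1.36 (percentile 94.99), immediate early and stress with 0.72, steroid cell regulators with 0.62, steroid synthesis with -0.91, chromaffin with -1.001, zona fasciculata with -1.38 and erythroid with -3.44. Endothelial with 0.75, splicing factor and RNA-binding with 0.53 and capsule and fibroblast with 0.41 lay inside as well.

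**Figure D4:**
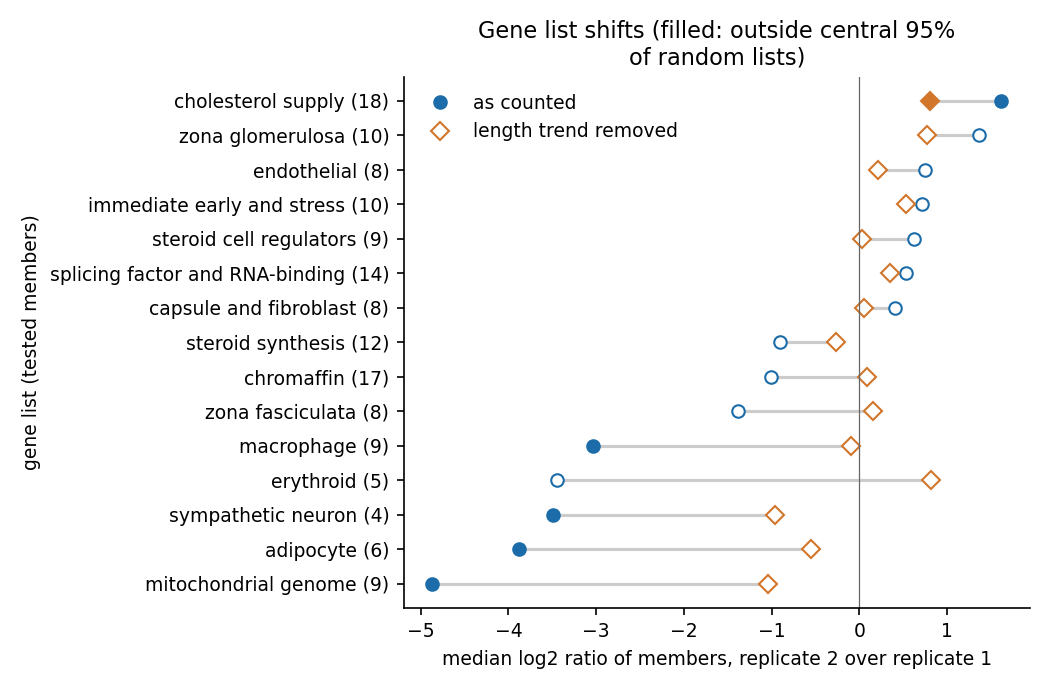
Median log2 ratio of replicate 2 over replicate 1 for the tested members of each list, as counted (circles) and with the length trend removed (diamonds); filled symbols lie outside the central 95% of 10000 random lists. As counted 5 lists lie outside, and with the trend removed only cholesterol supply does.

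The largest folds toward replicate 2 were partly a matter of which gene a model was assigned to. Zfp346 had 17 and 2401 reads (140.4-fold, 87.5 to 241), of which 2319 in replicate 2 belonged to a single-exon model on chromosome 13 from 55185029 to 55187844, 50204 bp outside the gene. At that place replicate 1 had 765 reads on an intergenic model from 55184731 to 55187607, which stood at 944 CPM against 3945 CPM in replicate 2, so most of the fold of Zfp346 comes from the assignment. Gm28006 had 11 and 1252 reads on a model of 122 nt that lies inside the gene of the long noncoding RNA Neat1. Gm45837 had 2 and 155 reads and overlaps Pde2a, so its reads are uncertain. Hgs and Chtf8, with 1 and 88 and with 2 and 136 reads, each share their symbol and place with another gene identifier and are uncertain too. The scavenger receptor Scara5 was 48.2-fold higher in replicate 2 (13.0 to 404; 2 and 97 reads), and Txnip, an inhibitor of thioredoxin, 38.5-fold (25.3 to 61.8; 22 and 852 reads). Their length-adjusted log2 ratios were 3.80 and 4.21.

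Toward replicate 1, the 8 largest folds had 0 reads in replicate 2. With 3 reads in place of 0, Hypk, with 214 reads, was at least 71.7-fold higher in replicate 1. Ssr2, a subunit of the translocon-associated complex with 187 reads, was at least 62.7-fold higher. The binomial intervals allow smaller folds, with upper limits of replicate 2 over replicate 1 at 0.0173 for Hypk and 0.0198 for Ssr2. Hypk overlaps Serf2, so its reads are uncertain. The other genes were 0610009B22Rik (at least 31.5-fold), the cell cycle inhibitor Cdkn1a (30.5-fold), Ndufaf3 and Mrpl36 (29.8-fold each), Gadd45g (29.5-fold) and mt-Nd2 (28.2-fold), with 84 to 94 reads in replicate 1. Most of these genes have short models, of 961 nt in Hypk and 1059 nt in Ssr2, which the length trend favours in replicate 1. Without that trend the bounds fell to 5.06-fold for Hypk and 5.00-fold for Ssr2, and for the others they ran from 1.93-fold for 0610009B22Rik to 13.3-fold for Cdkn1a. Ndufaf3 overlaps Impdh2, so its reads are uncertain too.

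Isoform use was then compared. Hsd3b1 was the most abundant gene whose most used model was not an annotated one. In replicate 1, 9923 of its 11333 reads (87.6%, 95% Clopper-Pearson interval 86.9 to 88.2), and in replicate 2, 1995 of 2916 reads (68.4%, 66.7 to 70.1), had the junctions of the annotated transcript without the first exon, which lies at 98859672 to 98859794. The most read model of replicate 2 also had a last exon that reached to 98850052, past the annotated end at 98852194. Oaz1, the antizyme of ornithine decarboxylase whose translation uses a ribosomal frameshift, had 94.9% and 73.2% of reads without an annotated gap of 4 bp at 80828292 to 80828295. The cholesterol synthesis gene Dhcr7 had 55.4% and 77.1% of reads on a model that starts at 143830234 on chromosome 7, past the annotated first exon. Cyb561, a cytochrome of chromaffin granules, had 37.6% and 51.0% of reads on a model that starts at 105940164 on chromosome 11.

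**Figure D5:**
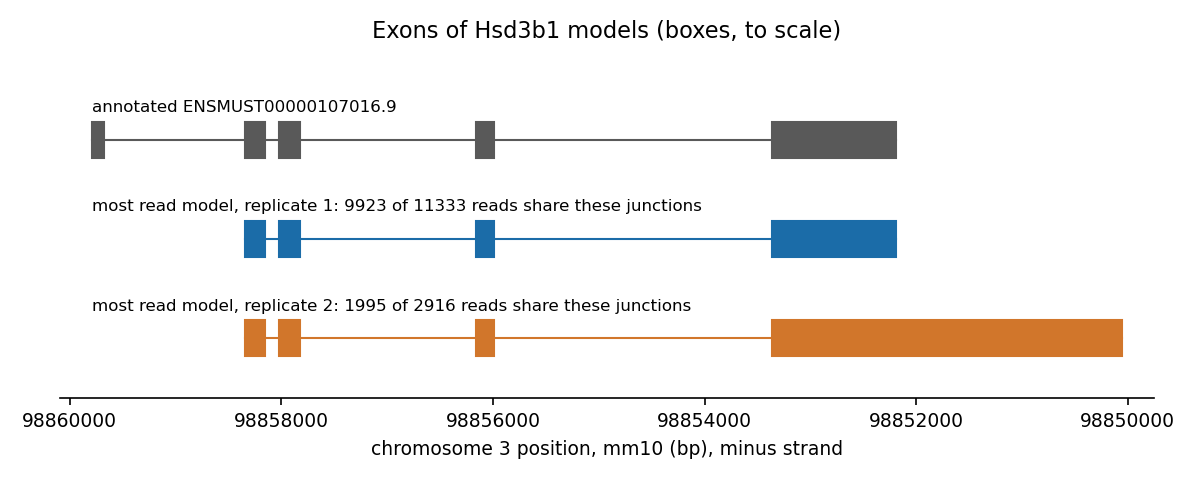
Exons (boxes, to scale) of Hsd3b1 models on chromosome 3 of mm10 (bp, minus strand, transcription from left to right): the annotated transcript and the most read model of each library. Both most read models lack the first annotated exon at 98859672 to 98859794, and that of replicate 2 has a longer last exon.

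Other genes of this kind included Hnrnpk, Hao2, Tacc1, Psmd1 and Kif5b, and the class was mixed. Hao2, a hydroxyacid oxidase, had 71.1% and 70.9% of reads on a model of 5 exons where the annotated transcript has 9. Tacc1 had 96.0% and 29.8% unspliced reads, and Kif5b, a kinesin, had 80.1% and 23.4% of reads on a model that lacks 6 junctions of the nearest annotated transcript. Among 1006 genes with at least 50 reads in each library, the most used model was annotated in 910 (90.5%), an incomplete match in 45, genomic in 28, a combination of known sites in 17 and a model with an unannotated site in 6. Of 101 list members with at least 10 reads in each library, 88 had an annotated most used model and 73 had the same one in both libraries. Cyp21a1 had 91.7% and 90.2% of reads on its most used annotated model, Cyp11b1 91.6% and 93.0%, and Star 85.5% and 92.8%.

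The most used model was the same in both libraries for 3673 of 4806 genes (76.4%, 75.2 to 77.6), and for 94.5% of 3028 genes with annotated models alone. A gene with a single such model agrees by construction, and among the 1950 genes with at least 2 annotated models the share was 91.4%. Fisher's exact test with Benjamini-Hochberg adjustment called 1397 of 4733 genes (29.5%), and 1164 of these by at least 20 percentage points. With annotated models alone it called 188 of 1950 genes. The test took no account of model length, so its calls cannot be told apart from the difference by length between the libraries. Where the annotated models of a gene spanned at least 500 nt, their mean length differed between the libraries in 1475 genes. It was longer in replicate 2 in 927 of these (62.8%, 60.3 to 65.3). The 8 largest differences were in Prickle1, Yod1, Nsd3, Rexo1, Ptpn11, Rdh13, Slc39a1 and Sdc4. In Prickle1, a planar polarity gene, all 17 reads of replicate 1 were unspliced against 0 of 47 in replicate 2. In Sdc4, a cell surface proteoglycan, the annotated model took 4 of 71 reads (5.63%) in replicate 1 and 63 of 64 (98.4%) in replicate 2. The phosphatase gene Ptpn11 had 105 of 111 reads on an incomplete match in replicate 1 and 0 of 11 in replicate 2. Prickle1, Nsd3, Rdh13, Slc39a1, Yod1 and Sdc4 had mostly unspliced reads in replicate 1, and Rexo1 and Ptpn11 mostly reads of an incomplete match there.

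Spliced models were then matched between the libraries by their junctions. Of 45908 unannotated spliced models of replicate 1, 23.0% (22.6 to 23.4) had the same junctions in replicate 2, and of 61783 in replicate 2, 17.1% (16.8 to 17.4) had them in replicate 1. The share grew with reads, from 16.4% and 10.3% at 1 read to 71.3% and 81.3% at 10 or more reads. Annotated spliced models of any read count matched in 67.7% and 70.1%. At equal reads they matched more often than unannotated ones, in 43.0% and 43.3% at 1 read and in 91.1% and 95.1% at 10 or more.

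Incomplete matches were also set against gene length, as shares of incomplete plus annotated reads, other classes left out. In replicate 1 these shares were larger in longer genes, with 2.62% for genes under 1000 nt (2.54 to 2.70) and 24.7% from 5000 nt (24.1 to 25.3). In replicate 2 the shares were 13.9% (13.1 to 14.6) and 21.1% (20.7 to 21.6), with the lowest, 8.24%, from 2500 to 3000 nt. Across genes the Spearman rho of share and length was 0.421 in replicate 1 (5929 genes) and 0.217 in replicate 2 (5440 genes). In replicate 1 the bin from 1500 to 2000 nt, at 15.8%, holds Hsd3b1, whose incomplete model is described above.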

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

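All tests in this part were chosen after the result they concern was seen. Unspliced reads on the strand opposite to annotated genes, which the comparison of genes left out and the structural classes above hold among antisense models, numbered 35688 in replicate 1 and 10877 in replicate 2, above the 3 reads that a count of 0 allows. Unspliced intergenic reads downstream of Zfp346 numbered 765 in replicate 1, and replicate 2 had 2319 reads there on a model assigned to Zfp346. With 1 group, no biological explanation was tested for any pattern below, and a difference between the animals stays open.

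The difference between the libraries followed transcript length, from an 18.2-fold median toward replicate 1 under 750 nt to a 2.98-fold median toward replicate 2 from 3000 to 4000 nt. For genes from 3000 nt, models lacking the 5' end held 7.86% of the reads on such models and annotated ones in replicate 1 and 7.54% in replicate 2, with the larger share in replicate 1 from 3000 to 4000 nt (7.61% and 5.73%) and in replicate 2 from 5000 nt (9.03% and 13.3%). Such reads still count for their gene, so shortening alone cannot lower its count, and only reads lost through shortening, which these shares do not measure, stay open. Recovery of molecules by length may have differed: within 124 genes with a short and a long annotated model, the long one had a log2 ratio higher by a median of 1.20 (bootstrap interval 0.40 to 2.11), against 5.01 between genes. The within-gene difference has the sign that recovery by length predicts, at a smaller size. A difference between the tissues in whole-gene levels alone is argued against in these 124 genes. The models of a gene would then share 1 ratio, and the interval lies above 0. A difference between the tissues in isoform use was not tested. How much of the trend between genes comes from recovery and how much from the tissues stays open.

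Cyp11b2, the aldosterone synthase, was 11.9-fold higher in replicate 2, with 16 and 191 reads. The length trend is argued against at the annotated length of 1625 nt, because removing it left a log2 ratio of 5.66. Reads need not have that length. From 3000 to 4000 nt, the bin highest in replicate 2, the upper quartile of log2 ratios was 2.44, and Cyp11b2 had 3.53 as counted. A greater length would weaken the argument. A constant rate of Cyp11b1 reads assigned to Cyp11b2 is argued against too, because the ratio of Cyp11b1 to Cyp11b2 in replicate 1 was 7.37 times that in replicate 2 and the intervals did not overlap. Whether replicate 2 held more zona glomerulosa tissue stays open. The list, which includes Cyp11b2 itself, had a median of 0.77 with the trend removed (percentile 90.75), inside the central 95% of random lists. In the other direction, 2 members were called toward replicate 1. Called were Agtr1a at 1.73, Shh at 2.71 (1 and 20 reads), Wnt4 at -3.55 (20 and 4) and Kcnk3 at -2.51. The value of Kcnk3 rests on 3811 nt, although most of its reads were unspliced, on pooled models of which the shortest had 1054 nt. Not called were Agtr1b at 1.91, Nr4a2 at 0.93, Kcnk9 at 0.61, Dab2 at 0.11 and Hsd3b6 at -0.65.

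Reads on the strand opposite to genes formed the third pattern. For unspliced reads, a strand set at random may account for part, but the shares computed cannot decide it. They set unspliced antisense reads against unspliced genomic reads on the gene's strand. Unspliced reads of annotated and incomplete-match models were left out, so the shares are too high where a gene has such reads. So measured, the median share on the opposite strand was 54.8% over 568 genes in replicate 1 and 35.2% over 144 genes in replicate 2. For genes near an even split, a strand set at random cannot be told apart from antisense transcription by these shares. Tacc1 had 582 reads on the opposite strand beside 581 on its own in replicate 1, and 199 beside 92 in replicate 2. An even split was not seen in every gene. Hsd3b1 had 4 beside 606 and 2 beside 697, and 28.3% and 37.5% of genes had a share under 10% or over 90%. The median of replicate 2 lay outside the range of 40 to 60%, and 47.2% and 36.8% of genes lay between 30 and 70%. For spliced reads of antisense loci, 49.3% in replicate 1 (46.4 to 52.3) and 42.6% in replicate 2 (39.0 to 46.3) had only junctions annotated on the other strand, which leaves the source of the rest open. At the 5 most abundant spliced antisense loci seen in both libraries the shares were 94.4% (90.8 to 96.9) and 93.3% (81.7 to 98.6). Reads of the genes themselves given the opposite strand would give such shares. These loci are part of the totals above and held 237 of the 561 such reads in replicate 1 and 42 of 313 in replicate 2.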

How the results depend on the processing

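The removal of the length trend and the matching by junctions alone were chosen after seeing the data. Over 55 results, 260 alternative values were computed, and no list median outside the central 95% changed sign. Medians inside it did with the length trend removed, such as 0.09 for chromaffin, 0.16 for zona fasciculata and 0.82 for erythroid. Of the values that answer a comparison, 74 stayed on the same side or within the spread, 27 moved and 9 fell inside the central 95%; of the others, 145 stayed and 5 list levels moved. DESeq2 size factors and thinning of the larger library moved none of them past these limits. For the list medians, a change of scaling shifts all genes alike, so their percentiles cannot change. Such values count among those that stayed and show no stability. Total counts kept the number of genes differing within them, but the share higher in replicate 2 went from 46.2% to 55.9%. With 2 libraries, the 60 values that leave one out lie within the spread by construction and show no stability: they ran from 1.95% to 4.51% for antisense models, from 2.90% to 6.56% for known sites in an unannotated combination and from 2.47% to 5.14% for an unannotated splice site. The gene test had no value without a library.

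Stricter detection left fewer items by construction: 9461 and 8866 genes at 5 reads, 32920 and 30051 models at 2 reads, and 13412 and 11762 models at 5 reads. With models of at least 2 reads, annotated models took 79.6%, incomplete matches 8.53% and models with an unannotated splice site 1.85% of reads. With multi-exon models these were 79.9% for annotated, 0.117% for antisense, 0.0304% for intergenic and 0.0933% for genomic models, since most reads of the latter classes are unspliced. Genes differing numbered 4037 of 4705 with at least 50 reads, where fewer were tested, 3890 with the length trend removed and 3143 with the mean length of all models.

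With the length trend removed, the list medians were -0.97 for sympathetic neuron, -0.0921 for macrophage, -0.55 for adipocyte and -1.04 for mitochondrial genome. With the mean length of all models they were -0.86, -0.14, -0.14 and -0.84, and 0.60 for cholesterol supply. The most used model was the same in 71.4% of genes at 5 reads, 86.4% at 50 reads, 94.5% with annotated models (91.4% where a gene had at least 2) and 84.2% without incomplete matches. Isoform use differed in 445 of 1001 genes at 50 reads, a share of 44.5% in place of 29.5%, in 188 of 1950 with annotated models (9.64%) and in 784 of 3945 without incomplete matches (19.9%). Unannotated models matched in 0% by identifier in each library, since identifiers are not shared, and in 42.4% and 39.6% with at least 2 reads. Beyond what the construction shows, the cause was not tested. Depth limits genes under 3 reads, 3.70 and 5.10 CPM.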

Other observations

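No test in this part was run beyond those given above. Spliced reads outside annotated genes fell on 173 intergenic loci in replicate 1 and 106 in replicate 2, of which 33 overlapped between the libraries. The most abundant one lay on the minus strand of chromosome 7 from 48124177 to 48132210, 6736 bp from Gm28665, with 3 reads in replicate 1 and 40 in replicate 2. A locus of up to 7 exons lay on the plus strand of the X chromosome from 137358510 to 137484644, 85964 bp from the synaptic gene Il1rapl2, with 14 and 5 reads. One of up to 5 exons lay on the plus strand of chromosome 17 from 17005114 to 17041386, 22727 bp from Zfp960, with 5 and 9 reads. The other two lay on chromosome 17 from 34996732 to 35001412, opposite to the tRNA synthetase gene Vars, with 10 and 10 reads, and on chromosome 13 from 55184731 to 55189153, 15972 bp from the receptor gene Fgfr4, with 10 and 5 reads. The last of these is the place downstream of Zfp346 where unspliced reads numbered 765 and 2319.

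Spliced antisense loci numbered 516 in replicate 1 and 489 in replicate 2, and 74 overlapped between the libraries. The most abundant lay opposite to Mc2r, the corticotropin receptor gene, on chromosome 18 from 68406907 to 68429320, with 132 and 12 reads. Loci opposite to Ccdc80 (47 and 10 reads), the histocompatibility gene H2-K1 (20 and 14), the survival gene Bcl2l1 (27 and 4) and Lyrm4 (25 and 5, where Fars2 lies on the same strand as the reads) followed. Since strand is uncertain for such reads, these values count reads and not antisense transcripts.

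Among list members, Kcnk3, the potassium channel gene, had 94.1% unspliced reads in replicate 1 (95% Clopper-Pearson interval 91.5 to 96.1) and 89.4% in replicate 2 (84.5 to 93.1). Th had 90.3% and 59.7% of reads on its most used annotated model, and Nr5a1 23.4% and 64.1%.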
